A study of Oncorhynchus mykiss with 47 samples.

How the data were processed

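Gill RNA of 47 juvenile Oncorhynchus mykiss (steelhead) was measured on salmonid oligonucleotide arrays, 4 to a slide, on 12 slides. Each array compared the Cy5-labelled RNA of 1 fish with a Cy3-labelled reference pool of 14 labelled samples, with the dyes always the same way round, so an effect of the dye stays in every ratio and cancels between groups. Per the file headers, the scanner files hold raw spot and local background intensity, quantified by the authors with ImaGene 8.0.1 and not background-corrected or normalized. The deposited value table holds log2 ratios of sample over reference. Its direction was checked from the values: each of the 47 columns correlated best with the ratio computed here for its own array (lowest r 0.943, highest r with another array 0.610, across 8097 bright probes). Each probe of that table has a median of 0 and the normalization behind it stays unknown, so it served as an alternative only. One array position on the slides was not used here.

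Spot mean intensities were background-corrected with normexp (offset 50) and normalized within each array by loess in limma 3.58.1 under R 4.3.3. Tables were read with the package data.table (version 1.17.8), and statmod 1.5.0 was loaded by limma. Spots marked as poor in the Cy5 image were left out unless saturated, those marked as empty were kept, and 0.437 to 1.66% of the spots of an array were removed. A probe was tested when its Cy5 intensity exceeded the 95th percentile of the 153 negative control spots of the same array on at least 5 arrays. Of 43689 probes, 34874 passed and 34800 could be fitted in every group. The median Cy5 spot intensity per array ran from 308 to 490, and 52.9 to 73.5% of probes per array lay above the negative controls. The number of arrays per group limits the precision.

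The model held the 6 groups and sex, fitted to all 47 arrays by least squares probe by probe with missing spots left out, followed by limma's moderated test with trend and robust settings. Probes with a Benjamini-Hochberg adjusted p under 0.05 were called. The 11 comparisons, their tests, the detection filter, the gene lists and the rule for naming genes were fixed before the data were examined. That rule took, among called probes with exactly 1 annotated gene, the 12 largest differences each way between migrants and residents and the 5 largest each way elsewhere, up to 4 called members of each list, and the glucocorticoid receptor and other named transport and hormone genes whatever their p. Gene names came from the RefSeq accessions that 112 probes carry. Of these, 105 matched a gene of the rainbow trout annotation, 76 were detected and 74 were tested. The other probes are given by their identifiers, because the files used here do not pair them with genes. Where the text says that a value was adjusted over the 74 named probes alone, that adjustment was chosen after the values were seen.

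Of 24 fixed gene lists, 5 had a member among the named probes: interferon and antiviral (eif2ak2), acute phase and inflammation (cfbl, leap-2b, il6 and il-17a), B cells (pax-5), ionocytes and ion transport (atp6v0cb), and endocrine receptors (2 nr3c1 probes). Only the acute phase list reached the 3 genes needed for camera (preset correlation 0.01, with an estimated correlation and fry beside it). The other 19 lists could not be tested. On simulated data with planted differences, the comparison of migrants with residents recovered 18.3% of differences of 0.5, 71.6% of 1 and 96.7% of 2 on the log2 scale, with 11 false calls among 131. The simulated noise was independent between probes and arrays and held no slide effect. Recovery on the real arrays may therefore differ from each simulated rate given here and below.

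Alternatives were no background correction, spot medians, median centring in place of loess, quantile normalization of mean intensities, the deposited table, no detection filter or a stricter one, slide as a block, a replicate block, no sex term, array weights, a fit to the compared groups only, plain empirical Bayes, a minimum of 1.5-fold, the mean of all resident groups in place of 1, and leaving out each array in turn. Keeping the marked spots, and the share of detected probes as a covariate, were added after the counts of called probes were seen, the latter before its own result was. Relabellings with slide as a block were added after the correlations were seen. Exact permutation tests of score differences and of correlations between changes relabelled fish in every possible way.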

Results

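Gills were sampled from hatchery-raised steelhead around 2 releases into a creek. Hatchery fish were taken 13 days before release 1 (n = 10) and release 2 (n = 9). Residents were caught near the hatchery 8 days after release 1 (n = 5) and release 2 (n = 6), and again 48 days after release 2 (n = 6). Migrants were caught 8 days after release 2 in a trap at the creek mouth (n = 11). Every resident was rated 1, a typical parr, and every migrant 3, a typical smolt, while hatchery fish were mostly rated 2. Each group held both sexes. Place and method of capture and smolt rating differed between migrants and residents, so these cannot be separated from migration. Creek fish differed from hatchery fish in day and place of sampling and in the mix of ratings, which cannot be separated either. The words rose, fell and change below describe groups of fish, not the same fish followed over time. Among 34800 tested probes, 4 comparisons called 386 to 685 probes and the other 7 called 0 to 3.

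**Figure D1:**
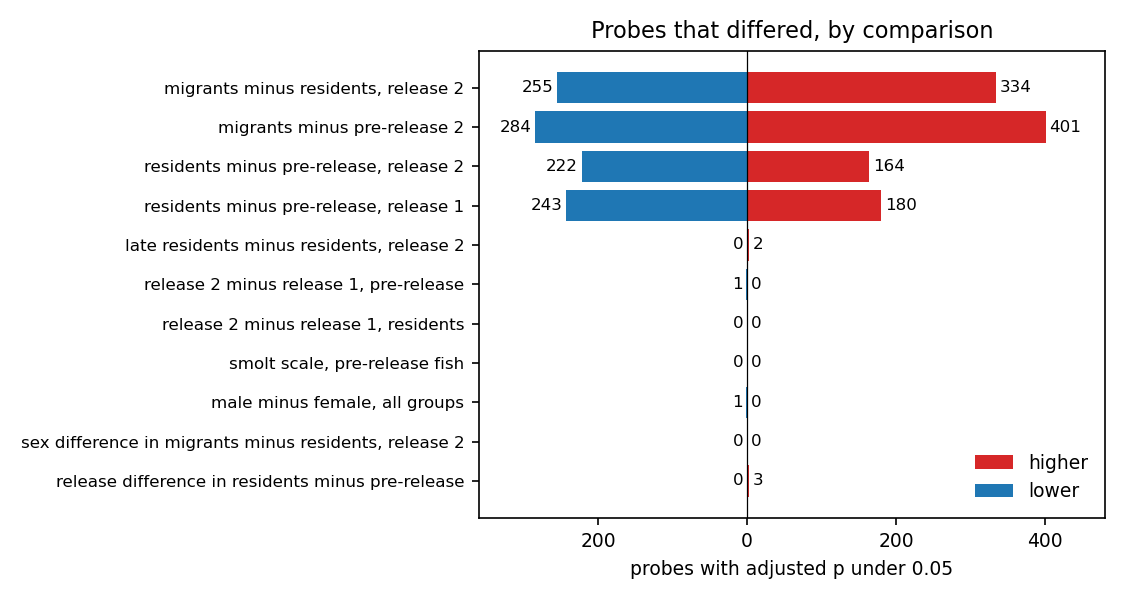
Probes with an adjusted p under 0.05 in each of the 11 comparisons (bars to the right, higher in the first group; to the left, lower; the axis counts probes). Migrants against residents of release 2 gave 334 higher and 255 lower.

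Migrants against residents of release 2 is the contrast of fish that left the creek with fish that stayed, at the same time after release. LOC100135979 was 3.19-fold lower in migrants (log2 difference -1.67, standard error 0.349, n = 11 and 6, adjusted p = 0.00529), below the resident mean in 11 of 11 migrants. The gene lmo2, a transcription cofactor of blood cell formation, differed by -0.67 (standard error 0.178, below the resident mean in 7 of 8 migrants read, adjusted p = 0.0387), and traf2, an adaptor of tumour necrosis factor receptors, by -0.61 (0.167, below it in 11 of 11 migrants, adjusted p = 0.0425), but without background correction it was -0.39 and did not pass (adjusted p = 0.101). LOC100136288 differed by -0.54 (0.147, below it in 9 of 11 migrants, adjusted p = 0.0409). Both probes of nr3c1, the glucocorticoid receptor, missed the threshold, at -0.28 (adjusted p = 0.517) and, for LOC100136786, -0.11 (adjusted p = 0.931); without background correction the former passed, at -0.35 (adjusted p = 0.0473). Adjusted over the 74 named probes alone, OMM-64, an otolith matrix protein gene, at 0.89, and LOC100135782, at 0.57, passed as higher in migrants (adjusted p = 0.0271 each), the latter at 0.86 in the deposited table and 0.35 with a replicate block. Over all probes both missed the threshold (adjusted p = 0.0833 for OMM-64 and 0.077 for LOC100135782). Among probes without a gene name, CUST_20587_PI417904088 was higher by 4.44 and CUST_40414_PI417904088 by 2.92, though the latter was read in only 6 migrants, 4 of them saturated, and 2 residents, while CUST_39310_PI417904088 differed by -2.20 and CUST_2651_PI417904088 by -2.13. In all, limma called 589 probes, 334 higher and 255 lower, with a median size of change of 0.673, and 393 changed at least 1.5-fold. Against the mean of the 3 resident groups, 2832 probes were called, 560 of them among the 589. That contrast adds residents of release 1 and late residents, so it is not matched in release or in days after release. With slide as a block, 358 probes were called (307 of them among the 589) and lmo2, traf2 and LOC100136288 no longer passed, at -0.70 (standard error 0.197), -0.63 (0.189) and -0.46 (0.149; adjusted p = 0.078, 0.0967 and 0.137); lmo2 was -0.42 with marked spots kept (adjusted p = 0.444). Over the 589 probes the median ratio of the difference with slide as a block to that without it was 0.983. The count was 309 without in_creek2 replicate 4, 316 without in_creek2 replicate 2, 168 with median centring (90 higher and 78 lower), 225 with only these groups in the fit and 150 with a replicate block, under which LOC100135979 also missed the threshold (adjusted p = 0.126).

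**Figure D2:**
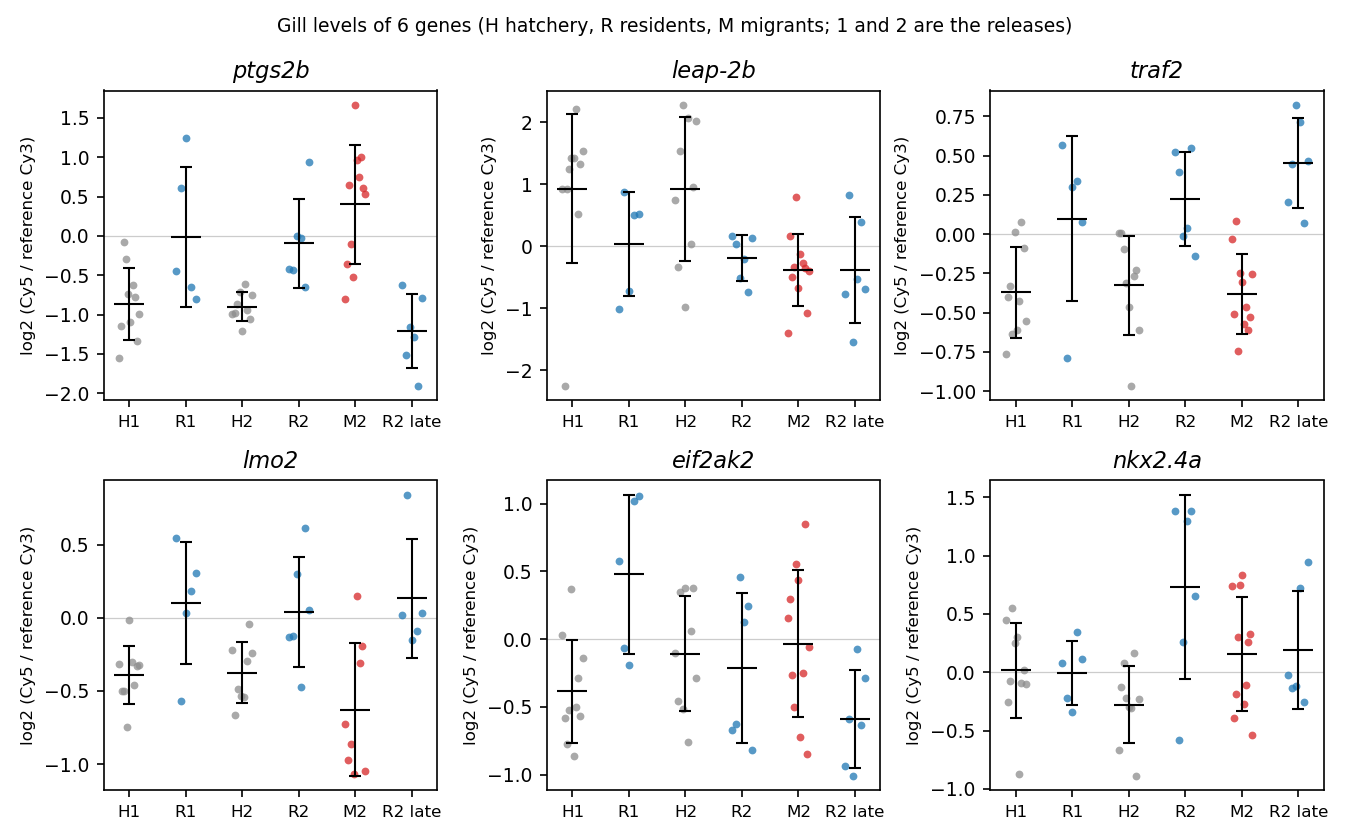
Log2 ratio of sample to reference pool for 6 genes in every fish (points), with the group mean and SD (lines); H is hatchery fish, R residents, M migrants, and 1 and 2 the releases. The traf2 means were -0.37 and -0.33 in hatchery fish, 0.10, 0.22 and 0.45 in the resident groups and -0.38 in migrants.

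Migrants were compared with hatchery fish of release 2, a different set of fish sampled before release. The gene ptgs2b, an inducible prostaglandin synthase, rose 2.45-fold (log2 difference 1.29, standard error 0.254, n = 11 and 9, adjusted p = 0.00152) and lay above the hatchery mean in 11 of 11 migrants. LOC100136615 rose by 2.25 (0.473, 9 migrants and 9 hatchery fish read, 1 of these hatchery fish saturated, adjusted p = 0.00426). LOC100135979 fell by 1.53 (0.310, adjusted p = 0.0025) and LOC100136288 fell by 0.64 (0.131, adjusted p = 0.00227), each below the hatchery mean in 11 of 11 migrants. The antimicrobial peptide gene leap-2b was lower by -1.30 (0.412), but was above the negative controls in only 6 of 11 migrants (8 of 9 hatchery fish), so that the size of the difference is uncertain; it passed when adjusted over the 74 named probes alone (adjusted p = 0.0437) and missed over all probes (adjusted p = 0.0962). In total limma called 685 probes, 401 higher and 284 lower, of which 450 changed at least 1.5-fold. The count with slide as a block was 345 (272 shared) and LOC100136615 missed the threshold at 2.205 (standard error 0.563, adjusted p = 0.0532). LOC100136615 was -0.64 on slide 4 and LOC100136288 was 0.08 on slide 6, against their called directions, and median centring gave 334 calls, 240 higher and 94 lower, and a replicate block 391.

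Residents of release 2 were compared with hatchery fish of the same release, sampled before it. The homeobox gene nkx2.4a rose 2.01-fold (log2 difference 1.01, standard error 0.245, n = 6 and 9, adjusted p = 0.0274), above the hatchery mean in 5 of 6 residents. It was the 1 named gene to pass. The gene traf2 was higher by 0.55 in 6 of 6 residents but missed the threshold (adjusted p = 0.107), and ptgs2b, at 0.80, and leap-2b, at -1.11, missed it as well (adjusted p = 0.188 and 0.293). The probe CUST_10210_PI417904088 rose by 3.33 and CUST_25670_PI417904088 by 2.36, while CUST_9502_PI417904088 fell by 2.63. Limma called 386 probes, 164 higher and 222 lower, of which 291 changed at least 1.5-fold. With slide as a block the count was 162 (116 shared), while array weights gave 631, median centring 77, of which 45 higher and 32 lower, only these groups in the fit 256 and a replicate block 225. The count fell to 144, 193, 194 and 257 without in_creek2 replicates 4, 5, 2 and 1 and to 231 without pre-release2 replicate 4, and nkx2.4a missed the threshold without in_creek2 replicate 2, 4 or 6 or pre-release2 replicate 8 (adjusted p = 0.0875, 0.0998, 0.0825 and 0.0561).

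Residents of release 1 were compared with hatchery fish in the same way. LOC100135979 rose 2.64-fold (log2 difference 1.40, standard error 0.377, n = 5 and 10, adjusted p = 0.0487), in 5 of 5 residents. In residents of release 2 it differed from hatchery fish by 0.15 and did not pass (adjusted p = 0.915). A test of the difference between the releases passed for 0 of the 74 named probes, over all probes or the named ones alone. Adjusted over the 74 named probes alone, eif2ak2, an antiviral kinase induced by interferon, passed as higher by 0.86 (0.253, 5 of 5 residents, adjusted p = 0.0241), while cck-t, a cholecystokinin gene, at -1.02, ywhag2, which encodes a 14-3-3 protein, at -1.04 but above the negative controls in only 2 of 5 residents, and LOC100136288, at -0.52, passed as lower (adjusted p = 0.0241, 0.0241 and 0.0292). Over all probes these 4 missed the threshold, at adjusted p = 0.0728, 0.0688, 0.0682 and 0.0919, although the first 3 passed without background correction, at 0.66, -0.81 and -0.68 (adjusted p = 0.031, 0.0328 and 0.0344). The probe CUST_21931_PI417904088, read in 3 of the 5 residents, fell by 4.73, and CUST_41402_PI417904088 rose by 2.17. Limma called 423 probes, 180 higher and 243 lower, of which 371 changed at least 1.5-fold. Slide as a block gave 66 calls (57 shared) and LOC100135979 missed the threshold at 1.91 (standard error 0.458, adjusted p = 0.0653), while median centring gave 77 higher and 61 lower probes and a replicate block 103. The count was 224, 885, 230, 270 and 202 without in_creek1 replicates 4, 5, 1, 6 and 3, and LOC100135979 passed in only 2 of 15 fits that each left out 1 fish (adjusted p = 0.0149 to 0.213).

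Fish of the 2 releases were different animals, so the change in residents could be compared between them. Of the 222 probes that were lower in residents of release 2, 206 (92.8%) also had a negative difference in residents of release 1, and of the 164 higher probes 130 (79.3%) had a positive one. Both releases called 41 lower probes, where 1.55 would be shared by independent draws, and 7 higher probes, where 0.848 would. The calls were not independent draws, however. Both comparisons took the spread of a probe from the same fit, so probes of low spread can be called in both without a shared change. Across 28785 probes, which are not independent replicates, the change in residents of release 2 correlated with that of release 1 at r = 0.322 (exact p = 0.00133 over all 3003 relabellings of the release 1 fish, 1 of 3 relations tested, adjusted p = 0.004), and the change in migrants correlated with it at 0.195 (exact p = 0.00833, adjusted p = 0.0125). The difference of migrants from residents correlated at -0.153, which did not pass (exact p = 0.109, adjusted p = 0.109). None of the 3 passed two-sided with slide as a block in every relabelling, at 0.237 (two-sided p = 0.0506, adjusted p = 0.152), 0.145 (p = 0.219, adjusted p = 0.219) and -0.135 (p = 0.111, adjusted p = 0.167). The first met the upper-tail criterion set beforehand, with 78 of 3003 relabellings as high.

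**Figure D3:**
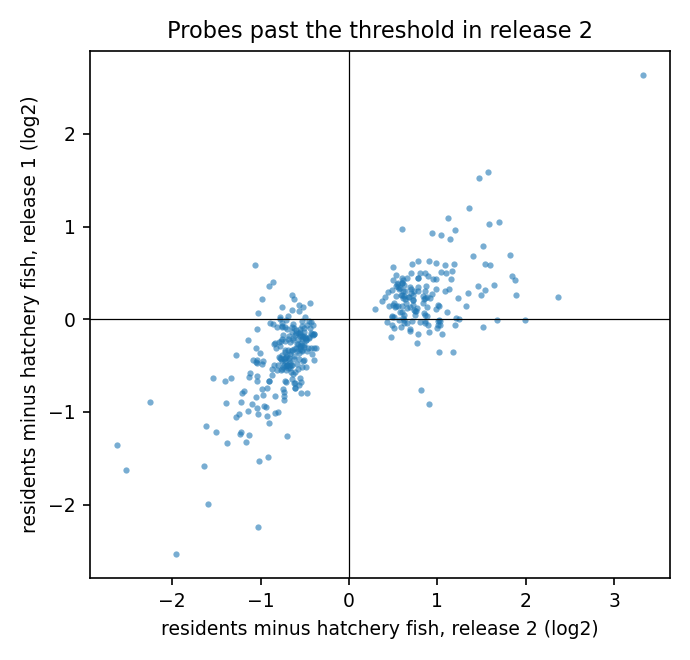
Log2 difference of residents from hatchery fish in release 1 (vertical axis) against release 2 (horizontal axis) for the 386 probes called in release 2 (points). Of the 222 lower probes, 206 lay below 0 in release 1 too.

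A migrant score was defined, after the probe counts were seen, as the mean log2 ratio of the 238 called probes with no missing spot that were higher in migrants than in residents of release 2 minus that of the 176 lower ones. Migrants and residents of release 2 defined it, at 0.884 (SD 0.254, n = 11) and -0.687 (SD 0.187, n = 6). Hatchery fish lay between them, at -0.0708 (SD 0.161, n = 10) before release 1 and -0.0092 (SD 0.160, n = 9) before release 2, a difference that did not pass an exact permutation test (0.0616, two-sided p = 0.411). Residents of release 1 stood at -0.387 (SD 0.161, n = 5), below their hatchery group by an exact permutation test (-0.316, p = 0.003, adjusted p = 0.006). Late residents stood at -0.846 (SD 0.146, n = 6), below hatchery fish of release 2 (-0.837, exact p = 0.0002, adjusted p = 0.0008) and below residents of release 1 (-0.459, exact p = 0.00649, adjusted p = 0.00865). These 4 differences, with slide as a block, were 0.0742, -0.422, -0.954 and -0.458 (standard errors 0.086, 0.111, 0.117 and 0.113), and on slides with both groups the last 3 were negative on every slide (-0.454 and -0.331; -1.02; -0.447, -0.301 and -0.539).

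**Figure D4:**
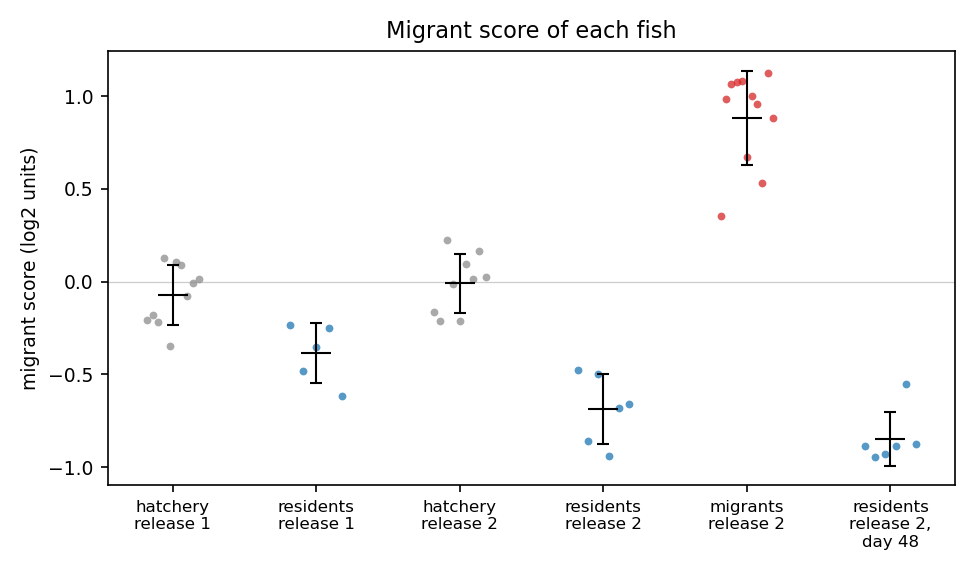
Migrant score (log2 units) of every fish (points), with the group mean and SD (lines). Fish of release 1, hatchery fish and late residents did not define the score.

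Late residents, 48 days after release 2, were compared with residents at 8 days. The gene ptgs2b was lower by -1.12 (standard error 0.325) in 6 of 6 late residents, which missed the threshold (adjusted p = 0.245). Limma called 2 probes, CUST_23247_PI417904088, which rose by 0.93 (adjusted p = 0.0165), and CUST_16038_PI417904088, which rose by 0.89 (adjusted p = 0.0251), and no probe fell. At an unadjusted p under 0.05 there were 2587 probes. The count was 0 with slide as a block, 44 with array weights, 28 without background correction, 25 from the deposited table and 9 with the share of detected probes as a covariate. It was 27, 14 and 4 without in_creek3 replicates 1, 3 and 5, and 13, 4, 1, 1 and 0 without in_creek2 replicates 3, 1, 4, 6 and 5.

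Hatchery fish of the 2 releases were compared to see whether they differed before release. The heat shock factor gene hsf1a was lower before release 2 by -0.62 (standard error 0.140, n = 9 and 10), in 9 of 9 fish, which passed when adjusted over the 74 named probes alone (adjusted p = 0.00393) and missed over all probes (adjusted p = 0.154), and it was -0.41 with slide as a block (adjusted p = 0.78). Limma called 1 probe, CUST_21313_PI417904088, which fell by 1.05 (adjusted p = 0.00284; saturated in 5 of the 8 fish read before release 1), among 1788 at an unadjusted p under 0.05. That count was 0 with slide as a block. It was 3 without pre-release2 replicate 1 and 2 without pre-release1 replicate 2, 4 or 8.

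Between residents of the 2 releases, limma called 0 probes, with 2899 at an unadjusted p under 0.05, and eif2ak2, at -0.70, missed the threshold (adjusted p = 0.472). Slide as a block gave 2 calls. The count was 23 and 12 without in_creek1 replicates 5 and 6 and 9 without in_creek2 replicate 5. The change from hatchery to creek differed between releases for 3 probes, CUST_25396_PI417904088 by 1.99 (standard error 0.335, adjusted p = 0.00503), CUST_7280_PI417904088 by 1.82 (0.325, adjusted p = 0.0302) and CUST_6168_PI417904088 by 1.57 (0.248, adjusted p = 0.00383), among 2316 at an unadjusted p under 0.05. All 3 were higher in residents of release 2 and lower in residents of release 1 than in their hatchery groups. CUST_7280_PI417904088 was read in only 3 residents of release 1 and 4 of release 2, and in 7 and 8 of their hatchery fish. With slide as a block 3 probes were called, 2 of them the same, and the count was 9 and 5 without in_creek1 replicates 5 and 6 and 6 without in_creek2 replicate 5.

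Hatchery fish were also compared by smolt rating, since the series names them as the fish whose local environment was most similar. The probe of nr3c1 at LOC100136786 had a slope of 0.81 per rating across 19 fish, which passed when adjusted over the 73 named probes tested here alone (adjusted p = 0.0499) and missed over all probes (adjusted p = 1). The slope was 0.49 without background correction, 0.44 with slide as a block, 1.24 from the deposited table and 1.22 in release 2 alone. Limma called 0 probes, with 1609 at an unadjusted p under 0.05. With slide as a block it called 1 probe, while hatchery fish of release 1 alone gave 8 and those of release 2 alone gave 4.

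Males and females were compared across all groups. Limma called 1 probe, CUST_6641_PI417904088, which fell by 0.48 in males (standard error 0.0855, adjusted p = 0.0382), among 1589 at an unadjusted p under 0.05, and no named gene passed. The call was lost with slide as a block, and 47 fits that each left out 1 fish gave 0 to 1 calls. For a sex difference in the contrast of migrants with residents, limma called 0 probes, with 1386 at an unadjusted p under 0.05 and 0 with slide as a block, and simulated differences of 2 on the log2 scale were recovered in 77.0% of cases and those of 1 in 11.9%.

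The fixed gene lists had few members. The acute phase list named PTGS2, which the trout symbol ptgs2b did not match. That gene, called by limma in migrants against hatchery fish (1.29, adjusted p = 0.00152), was therefore left out of the list and its tests. In the acute phase list as matched, 0 of 4 members passed over all probes in any comparison and 1, leap-2b, passed as lower in migrants than in hatchery fish when adjusted over the list alone. The list's camera test passed in 0 of 11 comparisons (lowest p 0.0563, 0.0598 with an estimated correlation, lowest adjusted p = 0.546), and the lowest fry p was 0.0188 for residents of release 2 against hatchery fish. Its member cfbl lay above the negative controls in only 4 of 10 hatchery fish of release 1 and 7 of 9 of release 2. Adjusted over the 11 comparisons, camera passed in 2 with slide as a block, as lower in residents of release 2 than in hatchery fish (unadjusted p = 0.00205) and as higher before release 2 than before release 1 (unadjusted p = 0.00207). Migrants against hatchery fish (unadjusted camera p = 0.032) and the release difference (0.0234) did not pass after that adjustment. The interferon, B cell and ion transport lists had 1 member each, so that adjusting over the list left p unadjusted. In residents of release 1 against hatchery fish, eif2ak2 (0.86) and pax-5, a transcription factor of B cells (0.38, above the negative controls in 3 of 5 residents and 5 of 10 hatchery fish), missed the threshold over all probes (adjusted p = 0.0728 and 0.371). The spot of atp6v0cb, a subunit of the proton pump, was read in only 3 migrants, 2 of them saturated, and in 1 fish of each resident group, too few to compare. For the endocrine list, 0 of 2 nr3c1 probes passed adjusted over the list alone in migrants against residents, and 1, at LOC100136786, passed for smolt rating. None of these passed over all probes.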

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

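The tests of detected share and of marked spots kept were chosen after the counts of called probes were seen, the former before its own result was and the latter after it.

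Among 104 groups of 4 to 10 fish checked for a fish far from the others, 11 (10.6%) had one, where chance gives about 5%. In hatchery fish of release 1, LOC100135979 was 1.10 in replicate 8 (others -1.20 to -0.251), CUST_2651_PI417904088 was 1.48 in replicate 5 (others -2.18 to -0.537), OMM-64 was -1.10 in replicate 2 (others -0.474 to -0.0118) and leap-2b was -2.26 in replicate 5 (others 0.519 to 2.22). In hatchery fish of release 2, replicate 3 stood apart for both nr3c1, at -0.976 (others 0.0502 to 0.588), and LOC100136615, at 1.49 (others -2.63 to -1.30). In residents of release 1, the nr3c1 probe at LOC100136786 was 0.925 in replicate 1 (others -0.642 to -0.227). In late residents, lmo2 was 0.844 in replicate 5 (others -0.150 to 0.0366), CUST_40414_PI417904088 was -0.632 in replicate 6 (others -2.27 to -2.19), CUST_39310_PI417904088 was -0.673 in replicate 2 (others 0.702 to 1.16) and the migrant score was -0.554 in replicate 5 (others -0.946 to -0.873).

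The change from hatchery to creek differed between the releases, by a test of the difference itself, for CUST_6168_PI417904088 (1.571), CUST_25396_PI417904088 (1.988) and CUST_7280_PI417904088 (1.819). For eif2ak2 the difference was -0.972, 0.86 in release 1 and -0.11 in release 2, which had an unadjusted p under 0.05, as the 1 member of its list, and missed the threshold over all probes (adjusted p = 0.593).

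Migrants and residents of release 2 differed at 589 probes. Slides argue against being the whole cause: with slide as a block, the median ratio of the blocked to the unblocked difference over these probes was 0.983 (5th to 95th percentile 0.812 to 1.15), and 584 kept their direction. The share of probes above the negative controls argues likewise, with a median ratio of 0.991 when it was a covariate, and keeping the marked spots gave 654 called probes. Of 100 regroupings of the same fish, the real one included, 1 called as many probes (589 against at most 40 in the others). That is the smallest share that 100 regroupings can give, so it argues against chance without excluding it. The regroupings moved fish freely between slides, so they do not test slide. Capture by trap at the creek mouth against electrofishing near the hatchery was confounded with migration, as was the smolt rating. The difference may reflect place, handling, smolt stage or migration, and no test here separates them.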

How the results depend on the processing

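Keeping marked spots, the covariate for detected share and the relabellings with slide as a block were chosen after the data were seen. The sign under alternatives was recorded for a set of named genes and probes, not for every value given in the text. Among the recorded values it was kept except for 1 probe. In migrants against residents, nr3c1 at LOC100136786, -0.11, was 0.001072 with array weights and 0.04255 without smolt_trap2 replicate 2, neither past the threshold (leaving out 1 array gave -0.2488 to 0.04255). Of 905 values of named genes and probes under an alternative or with 1 array left out, 790 kept their sign and their side of the threshold, 88 lost a call, 25 gained one and 2 changed sign. Only genes and probes called in the main fit could lose a call, so the 88 are not a share of all 905. Without leaving out arrays, calls ended in migrants against residents under 7 of 16 alternatives for lmo2 and for traf2, 5 of 16 for LOC100136288, 1 of 16 for LOC100135979 and CUST_2651_PI417904088, 2 of 16 for CUST_39310_PI417904088 and 1 of 14 for CUST_40414_PI417904088 (highest adjusted p = 0.444, 0.432, 0.15, 0.126, 0.154, 0.67 and 0.284), and elsewhere under 2 of 15 for LOC100136615 in migrants against hatchery fish, 3 of 15 for nkx2.4a in release 2 and 6 of 15 for LOC100135979 in release 1 (0.0594, 0.0911 and 0.226). Quantile normalization of mean intensities leaves log ratios unchanged by construction and moved nothing. Except where stated, the cause of a change was not tested.

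In the order migrants against residents of release 2, migrants against hatchery fish, residents against hatchery fish of release 2 and of release 1, the counts of 589, 685, 386 and 423 became 358, 345, 162 and 66 with slide as a block and 168, 334, 77 and 1.4e+02 (77 higher and 61 lower) with median centring, all of the latter among the original calls. Against the mean of 3 resident groups the first count was 2832, a contrast with more residents, which also differ in release and in days after release. With only the compared groups in the fit, and so fewer fish, the first was 225 and the third 256. Array weights gave 631 for the third. The minimum of 1.5-fold, a stricter call, left 450 of the second. With the replicate block the 4 counts were 150, 391, 225 and 103, but replicate numbers do not pair fish: correlations between fish of the same number passed 0.1 in at most 2 pairs of any comparison, and the block spends degrees of freedom.

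Late against early residents (2) gave 28 without background correction, 25 from the deposited table, 44 with array weights, 9 with the detected share as a covariate, 1 with the replicate block, and 0 with median centring, slide as a block, only these groups or plain empirical Bayes. Between hatchery groups, the count of 1 was 3 without background correction, 2 with the stricter filter or the replicate block, and 0 with spot medians, median centring, the deposited table, slide as a block or only these groups. Between residents of the releases, the count of 0 was 1 with spot medians, the deposited table, the replicate block or only these groups, 2 with slide as a block or array weights, and 4 with the detected share as a covariate. For smolt rating, the count of 0 was 1 with slide as a block, 8 in release 1 alone and 4 in release 2 alone. For sex, the count of 1 was 3 with median centring and 0 without background correction, with spot medians, the deposited table, marked spots kept, no detection filter, slide as a block, the replicate block, the detected share as a covariate or at least 1.5-fold. The release difference (3) was 1 with median centring. The acute phase list passed camera in 0 comparisons, and with slide as a block in 2, residents against hatchery fish of release 2 and the hatchery groups.

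Leaving out 1 array gave 309 to 785, 488 to 792, 144 to 433 and 202 to 885 for the 4 large counts, 0 to 27 for late residents, 1 to 3 for hatchery groups, 0 to 23 for residents of the releases, 0 to 0 for smolt rating, 0 to 1 for sex, 0 to 0 for the sex difference and 2 to 9 for the release difference. In migrants against residents, lmo2 lost its call without smolt_trap2 replicate 2, 6, 7, 8 or 9 or in_creek2 replicate 2, 3, 4 or 5 (adjusted p = 0.0521 to 0.148), traf2 without smolt_trap2 replicate 4, 5, 7, 8, 10 or 11 or in_creek2 replicate 1, 2, 4, 5 or 6 (0.0511 to 0.142), LOC100136288 without smolt_trap2 replicate 1, 2, 7, 8 or 10 or in_creek2 replicate 2, 3 or 4 (0.061 to 0.139), CUST_39310_PI417904088 without smolt_trap2 replicate 6, 7 or 10 or in_creek2 replicate 2, 4, 5 or 6 (0.0594 to 0.12) and CUST_40414_PI417904088 without in_creek2 replicate 2 (0.219). Probes near the negative controls limit what the arrays can show, since 52.9 to 73.5% of probes per array lay above them.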

Other observations

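The gene groups and the relabellings with slide as a block were chosen after the results were seen.

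Of 13 immune and inflammation genes grouped after the values were seen, traf2 passed as lower in migrants than in residents, and ptgs2b rose and leap-2b was lower in migrants than in hatchery fish, adjusted over the 74 named probes alone, as eif2ak2 was higher in residents of release 1 than in hatchery fish. In the other comparisons none passed. The means of leap-2b were 0.93 in both hatchery groups (SD 1.21, n = 10, and 1.16, n = 9), 0.03 and -0.19 in residents of release 1 and 2, -0.38 in migrants, of which only 6 of 11 lay above the negative controls, and -0.39 in late residents. The means of ptgs2b were -0.86 and -0.90 in hatchery fish, -0.01 and -0.09 in residents of release 1 and 2, 0.40 in migrants and -1.21 in late residents. Of 8 genes of hormones and their receptors, 0 passed between migrants and residents by limma, adjusted over the named probes alone, and their differences ran from -0.31 to 0.62. In the other comparisons cck-t passed as lower in residents of release 1 than in hatchery fish and nr3c1 at LOC100136786 as higher with smolt rating, adjusted in the same way.

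A candidate explanation for the change of residents after release 2 is a change that both releases share, and the correlation across probes with release 1 was 0.322, in the upper tail of all relabellings (-0.323 to 0.330). For migrants the same correlation was 0.195. The criterion set beforehand was the upper tail alone. With slide as a block in every relabelling, residents met it (0.237, 78 of 3003 relabellings as high) and migrants did not (0.145, 335 as high). Neither passed the stricter two-sided test with slide as a block (p = 0.0506 and 0.219). A change shared by fish that left the hatchery therefore stays undecided, since missing that test does not show that slide accounts for it. How far migrants differ from residents because residents changed stays open: that correlation, -0.153, lay inside the relabellings, while other values go with a change of residents. Of the 334 probes higher in migrants than in residents, 24.6% changed in the same direction in residents of release 1, and of the 255 lower ones 35.7%, with 12 of each called in the opposite direction and 1 of each in the same. Residents of release 1 also scored below their hatchery group (-0.316), and migrants, which helped to define the score, 0.894 above theirs.

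Hatchery fish rated closer to a smolt may already carry part of the migrant profile. The slope of the score was 0.106 per rating (95% interval -0.0448 to 0.257), which a permutation test did not pass (p = 0.123, 19 fish), and the interval reached past 0.223, the bound set beforehand from the gap of 0.894 between migrants and hatchery fish. With slide as a block the slope was -0.000118 (-0.124 to 0.123, 7 residual degrees of freedom), an interval that lies below that bound, so the fits with and without slide disagree on whether such a slope is excluded, and slide and rating cannot be told apart in so few fish.

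Regroupings of the same fish, 100 per comparison with the real one included, were counted when they called as many probes. For migrants against hatchery fish 1 did (685 against at most 6 in the others), for residents against hatchery fish of release 2 also 1 (386 against 4) and of release 1 also 1 (423 against 15). That is the smallest share that 100 regroupings can give, so it argues against chance without excluding it. Slide was not kept in the regroupings, so they do not test it. For late residents (3 did, 2 calls against at most 4), hatchery groups (3 did, 1 against 3), sex (4 did, 1 against 7) and the release difference (2 did, 3 against 3), the share lay under the bound set beforehand only with each comparison taken alone. These 4 counts give less ground against chance: other regroupings called as many or more, 11 comparisons were made, and the first 3 counts were 0 with slide as a block. Where nothing was called, every regrouping calls as many, so the count says nothing about chance: residents of the releases (100 did, 0 against 97), smolt rating (100, 0 against 12) and the sex difference (100, 0 against 16). The highest count for residents of the releases came from 1 regrouping, where the median of the others was 0, and whether a structure among those fish lies behind it was not tested.

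Across all arrays, the first component held 9.66% of the variance, the second 6.04% and the third 5.83%. Slide accounted for 70.4% of the second (permutation p = 0.0001, the smallest the permutations can give, adjusted p = 0.001) and group for 43.2% of it (adjusted p = 0.004). Group accounted for 69.3% of the third (p = 0.0001, adjusted p = 0.001), and for 38.0% of the first, where slide accounted for 50.9%. Group and slide overlap in part, so these shares do not add up.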
